A study of Mus musculus with 6 samples.

How the data were processed

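RNA was measured in CD11b+Gr-1+ cells sorted from the livers of C57BL/6 mice that carried EL4 tumours, a transplantable mouse lymphoma. The labels call these cells myeloid-derived suppressor cells (MDSC), a mixture of immature granulocytic and monocytic cells that restrain T cells. There were 6 arrays in 2 groups, 3 from mice given PBS and 3 from mice given concanavalin A (Con A), a plant lectin that activates T cells and causes acute hepatitis in mice. Cells were taken 3 hours after injection. The labels disagree on the dose of Con A, giving 12.5 mg/kg in the design text and 12.5 ug/kg in the treatment field, and the dose stays unsettled here. They also call the PBS samples untreated. They state 3 mice per group without saying that each array holds 1 mouse, so p-values measure the spread between these samples, which may be partly technical.

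Total RNA was amplified with a whole-transcriptome kit and labelled with biotin, per the labels' protocols. The deposited values are log2 expression values of a mouse Affymetrix gene array. RMA and Partek are named without versions or settings in the submitters' processing notes. RMA corrects background, brings arrays to a common distribution and summarises probes on the log2 scale. It compresses differences near the bottom and the top of the scale, so folds of dim genes and of the brightest genes are understated. Array medians lay between 7.05 and 7.08, and the highest values between 14.2 and 14.3. The deposited values carry no detection calls, and the number of arrays limits the precision.

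The value table had 35556 rows. The platform annotation gave 1 gene symbol to 21789 rows, several to 1621 and none to 12146. Symbols were compared with RefSeq gene names of assembly GRCm38.p6 through Entrez numbers. No symbol changed (0 updates), and 91 rows had a number outside that gene table and kept their symbol. Only rows with 1 symbol were tested. Where several rows shared a symbol, the row with the highest mean over the 6 arrays stood for the gene, which applied to 999 genes with 2850 rows. This left 19938 genes. All 7 named genes with several rows had their rows in 1 direction. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed. There were 0 identical pairs of arrays.

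Con A was compared with PBS by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the values as deposited, with Benjamini-Hochberg adjustment over all 19938 genes and a threshold of 0.05. A second count required a difference of at least 1 on the log2 scale (2-fold). Differences are Con A minus PBS, and intervals are 95% intervals of the moderated fit. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

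The design, the alternatives, the rule for named genes and 38 gene lists were fixed before the data were examined. The lists held 788 entries, of which 714 matched a tested gene, 1 of them through an older symbol. They covered NF-kB response, CD40 and TNF receptor signalling, cytokines, chemokines, chemoattractant receptors, type I interferon response, interferon-gamma response, suppressor function, antigen presentation, reactive oxygen genes, primary granules, secondary and tertiary granules, immediate early genes, feedback inhibitors, heat shock, apoptosis, pattern recognition, adhesion, coagulation, glycolysis and hypoxia, cell cycle, oxidative phosphorylation, ribosomal proteins, arginine and tryptophan metabolism, prostaglandin synthesis and the STAT3 and IL-6 response. The other lists were markers of granulocytic, monocytic, Kupffer, dendritic, T, NK, B, eosinophil with basophil and mast, hepatocyte, endothelial with stellate, erythroid and platelet cells. Genes can belong to several lists. Each list was tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 38 lists. Camera with an estimated correlation and fry stood beside it. Members past the threshold were counted over all genes and adjusted over the list alone.

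Named genes were fixed by rule. They were 14 genes that the study's title and design point to, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members of each list with the largest difference past the threshold. Where no member of a list passed, the 2 largest differences are given as values. Predicted genes, unnamed clones and small RNAs were left out of the largest changes. Ly6c1 is not analysed here.

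The fit was tested on simulated data with 19938 genes, of which 200 were changed in each of 10 simulations. It recovered 51.8% of genes changed by 0.5 on the log2 scale, 96.3% of those changed by 1 and 99.7% of those changed by 2. Of all calls 6.77% were false, and 0 had the wrong sign. The simulated noise was normal and independent between genes, with no array set apart. In the real arrays, genes of a list had a median estimated correlation of 0.358, so these rates need not hold there. Alternatives were the repeat number as a block, quantile normalization, a common median, filters at the 30th and 50th percentile of mean level, all rows of the table, the mean of a gene's rows, an intensity trend with a robust prior, array weights, an unmoderated test and each array left out in turn. The fit without both PBS replicate 3 and Con A replicate 2 was added after seeing the data.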

Results

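Gene expression was measured on 6 arrays of CD11b+Gr-1+ cells sorted from the livers of tumour-bearing mice, 3 after PBS and 3 after Con A. The title of the study concerns acute hepatitis, the maturation of these cells, their suppressor function and the receptor CD40. The comparison asks which transcripts differed in the sorted cells 3 hours after Con A. Levels are log2 values, given as mean ± SD with n = 3 per group.

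After Con A, 15 of 17 measured interferon-gamma targets, 10 of 25 cytokine genes and 8 of 25 chemokine genes rose and 0 fell, while 4 of 16 monocytic markers fell and 2 rose. These 4 lists passed with camera at its preset correlation and lost that call at adjusted p = 0.715, 0.715, 0.762 and 0.762 with an estimated correlation. Il1a, which encodes interleukin-1 alpha, was 18.1-fold higher, at 11.44 ± 0.68 after Con A and 7.26 ± 1.00 after PBS. Ccr2, the receptor that brings monocytes into tissue, was 4.01-fold lower, at 8.77 ± 0.40 against 10.77 ± 0.27. The granulocyte genes Ly6g, S100a8 and S100a9 differed by -0.09, -0.04 and 0.03 on the log2 scale, and none passed the test (adjusted p = 0.566, 0.803 and 0.834 by limma).

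Of 19938 genes, 2355 differed between Con A and PBS by limma after Benjamini-Hochberg adjustment, 915 higher and 1440 lower after Con A. A difference of 2-fold or more was found for 412 of them, 240 higher and 172 lower. Differences over 4-fold were found for 45 higher genes and 6 lower genes. The groups did not overlap in 29.9% of all genes, where chance gives 10%. Without PBS replicate 1 the count of genes was 1140, without Con A replicate 2 it was 1272 and without Con A replicate 3 it was 1480. The unmoderated test gave 671.

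The 10 largest rises were those of Il1a, Ccl24, Lipg, Slc7a2, Gbp4, Cxcl11, Cxcl10, Gbp5, Socs1 and Iigp1. Il1a (probe set 10487588) rose by 4.18 (95% interval 2.97 to 5.38, adjusted p = 0.00286). Ccl24, which encodes the eosinophil attractant eotaxin-2, rose by 3.78 ± 0.26 (SE), and Lipg, which encodes endothelial lipase, by 3.66 ± 0.35 (SE). Slc7a2, a transporter of arginine, rose by 3.66, from 6.89 ± 0.82 to 10.54 ± 0.42. Socs1 (probe set 10437668), a feedback inhibitor of cytokine receptors, rose by 3.23 (95% interval 2.94 to 3.51, adjusted p = 0.000251). Gbp4 and Gbp5, which encode guanylate-binding proteins, rose by 3.49 and 3.34, and the chemokine gene Cxcl11 and the GTPase gene Iigp1 by 3.45 and 3.20. Cxcl10, a chemokine gene induced by interferon, rose 10.3-fold, from 10.21 ± 0.76 to 13.58 ± 0.13.

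The 10 largest falls were smaller. Pid1 (probe set 10356172) fell by 2.36, from 9.94 ± 0.28 to 7.58 ± 0.15 (adjusted p = 0.000519). Cd180, a Toll-like receptor homologue, fell by 2.27, and Sh2d1b1, a signalling adaptor, fell by 2.17. F13a1, which encodes a coagulation factor subunit made by monocytes, fell by 2.16, and Otulinl fell by 2.03. Ccr2 fell by 2.00 (adjusted p = 0.00177). Cd300lb fell by 1.91, Cdca7 by 1.84, Abi3 by 1.83 and Smad3, a mediator of TGF-beta signals, by 1.82.

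**Figure D1:**
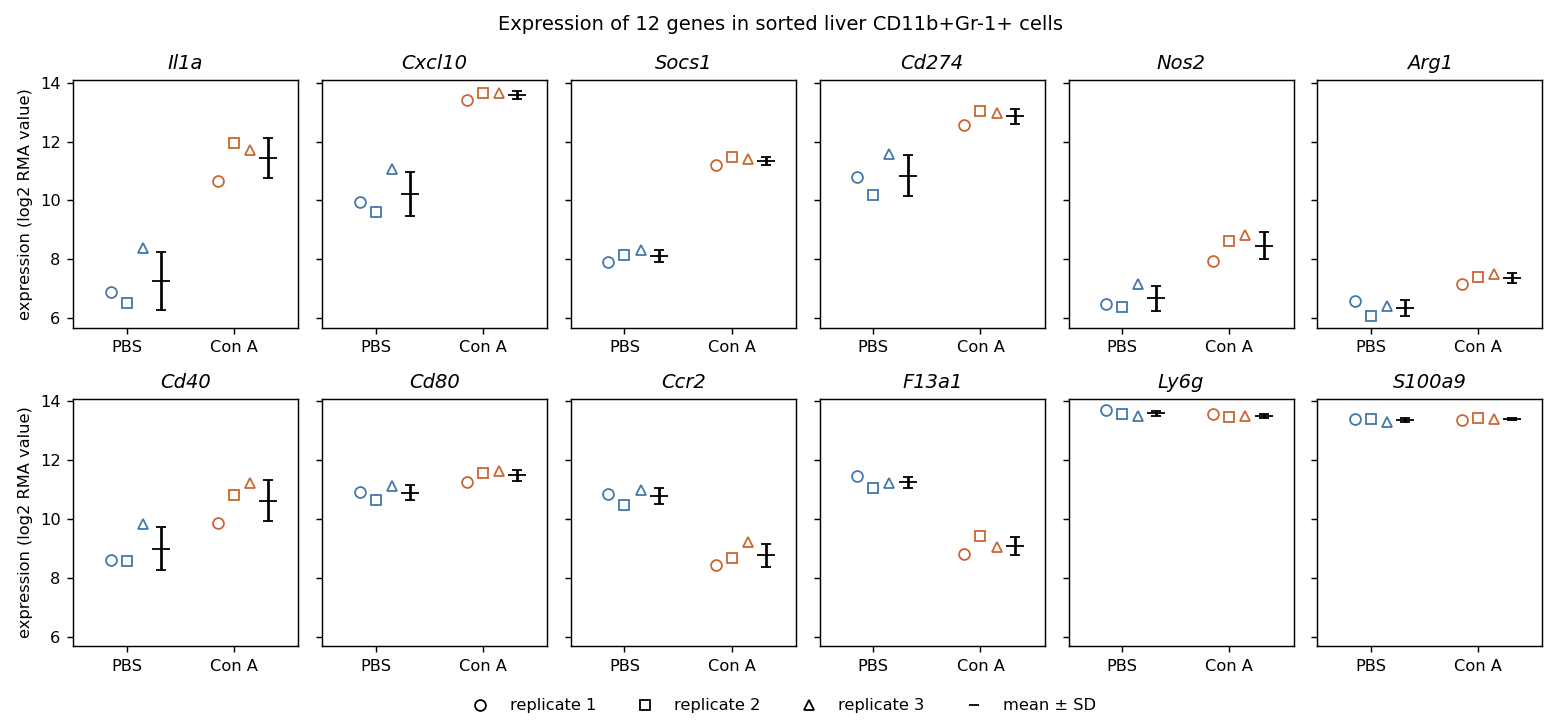
Expression of 12 genes (log2 RMA value, vertical axis) in each PBS and Con A array, with symbols for the replicate and bars for mean ± SD. Il1a, Cxcl10 and Socs1 lie higher in all 3 Con A arrays, Ccr2 and F13a1 lie lower, and Ly6g and S100a9 lie near the top of the scale in both groups.

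Of the 14 genes that the study's title and design point to, 13 were measured. Cd274, which encodes the checkpoint ligand PD-L1, rose 4.07-fold, from 10.84 ± 0.70 to 12.86 ± 0.26 (adjusted p = 0.00763). Nos2, inducible nitric oxide synthase, rose 3.44-fold (limma adjusted p = 0.0063), and Arg1, arginase 1, rose 2.00-fold from 6.35 ± 0.27 to 7.36 ± 0.17 (limma adjusted p = 0.00575). The Arg1 level lay below the array medians of 7.05 to 7.08 after PBS and not far above them after Con A. Without detection calls, its expression in these cells is not established. Cd80, a costimulatory ligand, rose 1.5-fold with an adjusted p of 0.0464, which became 0.136 without PBS replicate 1, 0.109 without PBS replicate 2, 0.16 without Con A replicate 2 and 0.143 without Con A replicate 3. Cd40 (probe set 10478678) was 3.09-fold higher, at 10.63 ± 0.69 against 9.0 ± 0.72, and missed the threshold (adjusted p = 0.0509). Its level was 9.83 in PBS replicate 3 and 9.86 in Con A replicate 1, and without PBS replicate 3 the adjusted p was 0.00795. Cd86, Ptgs2, Il10, Cybb and Itgam did not pass the test, with differences of 0.11 (95% interval -0.80 to 1.01), 0.72 (-0.78 to 2.23), 0.67 (-0.03 to 1.38), 0.07 (-0.12 to 0.26) and -0.15 (-0.37 to 0.06). With 1 array left out, Ptgs2 ranged from 0.11 (without PBS replicate 2) to 1.42 (without PBS replicate 3), Cd86 from -0.19 (without Con A replicate 3) to 0.46 (without Con A replicate 1), and Il10 from 0.37 (without Con A replicate 3) to 0.93 (without PBS replicate 3). Cybb ranged from 0.03 (without PBS replicate 3) to 0.11 (without PBS replicate 1) and Itgam from -0.23 (without PBS replicate 3) to -0.08 (without PBS replicate 1). With the replicate number as a block, Il10 and Cd40 passed the test (adjusted p = 0.00505 and 0.00331). Cd40 missed it in 9 of its 17 alternatives, with adjusted p up to 0.227.

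The interferon-gamma response had the largest median difference among the lists past the threshold. Of its 17 measured members, 15 rose and 0 fell (16 rose adjusted over the list alone), with a median difference of 1.61. Camera gave an adjusted p of 6.8e-16 at the preset correlation, and adjusted p = 0.715 with an estimated correlation. Gbp4, Gbp5, Socs1 and Iigp1 led the list. Of 22 type I interferon response genes, 5 rose and 0 fell (9 adjusted over the list alone), with Zbp1 at 1.57, Stat2 at 1.21, Irf7 at 0.77 and Ddx58 at 0.46. Its camera adjusted p was 5.8e-05, against adjusted p = 0.762 with an estimated correlation. In PBS replicate 3 the mean of the interferon-gamma list lay 0.51 above the PBS mean, and that of the NF-kB list 0.52 above it. The type I interferon list lay 0.56 above it there, higher than in Con A replicate 1, at 0.10, so its arrays overlapped between the groups.

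Of 21 NF-kB response genes, 14 rose and 0 fell (16 adjusted over the list alone), with a median of 0.96. Camera gave 2.7e-11, and adjusted p = 0.762 with an estimated correlation. Icam1, an adhesion molecule, rose by 1.90, the NF-kB inhibitor Tnfaip3 by 1.74, Ier3 by 1.44 and the subunit Relb by 1.20. Of 20 genes of CD40 and TNF receptor signalling, 4 rose and 2 fell (6 and 3 adjusted over the list alone), and the list missed the threshold (camera adjusted p = 0.092). Tnfrsf26, the death receptor gene Fas and the adaptor Traf6 rose by 1.20, 1.09 and 0.89, while Map3k14, the kinase NIK of the noncanonical NF-kB pathway, fell by 0.68. Without PBS replicate 3 this list had an adjusted p of 0.00679, and without Con A replicate 1 of 0.0317.

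Among 25 cytokine genes, 10 rose and 0 fell (12 adjusted over the list alone). Camera gave 3.1e-06, and adjusted p = 0.715 with an estimated correlation. After Il1a came Il6, which rose by 2.93 from 5.63 ± 0.88 to 8.56 ± 0.78, Il12a by 1.40 and Csf1 by 1.34. Among 25 chemokine genes, 8 rose and 0 fell (8 adjusted over the list alone), led by Ccl24, Cxcl11, Cxcl10 and Cxcl9, the last by 3.14. Camera gave 1.1e-05, and adjusted p = 0.762 with an estimated correlation. Of 15 chemoattractant receptor genes, 1 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.566). Ccr2 and the fractalkine receptor gene Cx3cr1 fell by 2.00 and 1.81, Cxcr4 fell by 0.76, and the complement receptor gene C3ar1 rose by 1.26.

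Feedback inhibitors of signalling rose in 9 of 24 cases and fell in 1 (13 and 2 adjusted over the list alone). Camera gave 6.5e-06, and adjusted p = 0.762 with an estimated correlation. Besides Socs1, the STAT5 target Cish rose by 1.83 and Tnfaip3 by 1.74, while the ERK phosphatase gene Dusp6 fell by 1.39. Of 21 immediate early genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone), with Maff at 1.36, Myc at 0.96, Klf2 at 0.52 and Fos at -0.74. The list mean of PBS replicate 3, 0.42 above the PBS mean, exceeded those of Con A replicates 1 and 2, 0.10 and 0.31 above it. The camera adjusted p was 0.0469, against adjusted p = 0.807 with an estimated correlation, and it was 0.149 without PBS replicate 1, 0.301 without PBS replicate 2 and 0.348 without Con A replicate 3. Of 21 genes of the STAT3 and IL-6 response, 7 rose and 2 fell (8 and 2 adjusted over the list alone). Its camera adjusted p was 0.0148, against adjusted p = 0.762 with an estimated correlation, and it was 0.0567 without PBS replicate 1, 0.0894 without PBS replicate 2 and 0.0813 without Con A replicate 3. Its mean in PBS replicate 3, 0.37 above the PBS mean, exceeded that in Con A replicate 1, 0.19 above it. In this list the kinase gene Pim1 rose by 1.12 and Bcl3 by 1.05.

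Of 24 genes of suppressor function, 9 rose and 0 fell (9 and 1 adjusted over the list alone). Camera gave 0.00085, and adjusted p = 0.715 with an estimated correlation. Slc7a2, Cd274, Nos2 and Arg1 led the list. Of 17 genes of arginine and tryptophan metabolism, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with Wars, a tryptophanyl-tRNA synthetase gene, at 1.79. Camera gave 0.0033, and adjusted p = 0.762 with an estimated correlation. These lists share the entries Slc7a2, Nos2, Arg1, Arg2 and Ido1. Fry, which asks if the members of a list move on balance in 1 direction, called 2 lists, interferon-gamma response (adjusted p = 0.0289) and suppressor function (0.0376).

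Of 18 antigen presentation and costimulation genes, 1 rose and 0 fell (3 and 0 adjusted over the list alone), and Cd80 was that gene. The list had a median of -0.17 (-0.31 without PBS replicate 2 and 0.07 without PBS replicate 3), a mean of 0.08 and an upward camera direction (adjusted p = 0.676), so these differed in sign, and without PBS replicate 3 the adjusted p was 0.0413. Its mean lay 0.65 above the PBS mean in PBS replicate 3 and 0.63 above it in Con A replicate 3. Of 24 genes of pattern recognition and inflammasomes, 11 rose and 6 fell (12 and 8 adjusted over the list alone; camera adjusted p = 0.092). The cytosolic sensor gene Nod2 rose by 1.53 on the log2 scale, the inflammatory caspase gene Casp4 2.83-fold and the beta-glucan receptor gene Clec7a by 1.34, while Tlr9 fell by 1.35. This list had an adjusted p of 0.00318 without PBS replicate 3 and 0.0226 without Con A replicate 1.

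**Figure D2:**
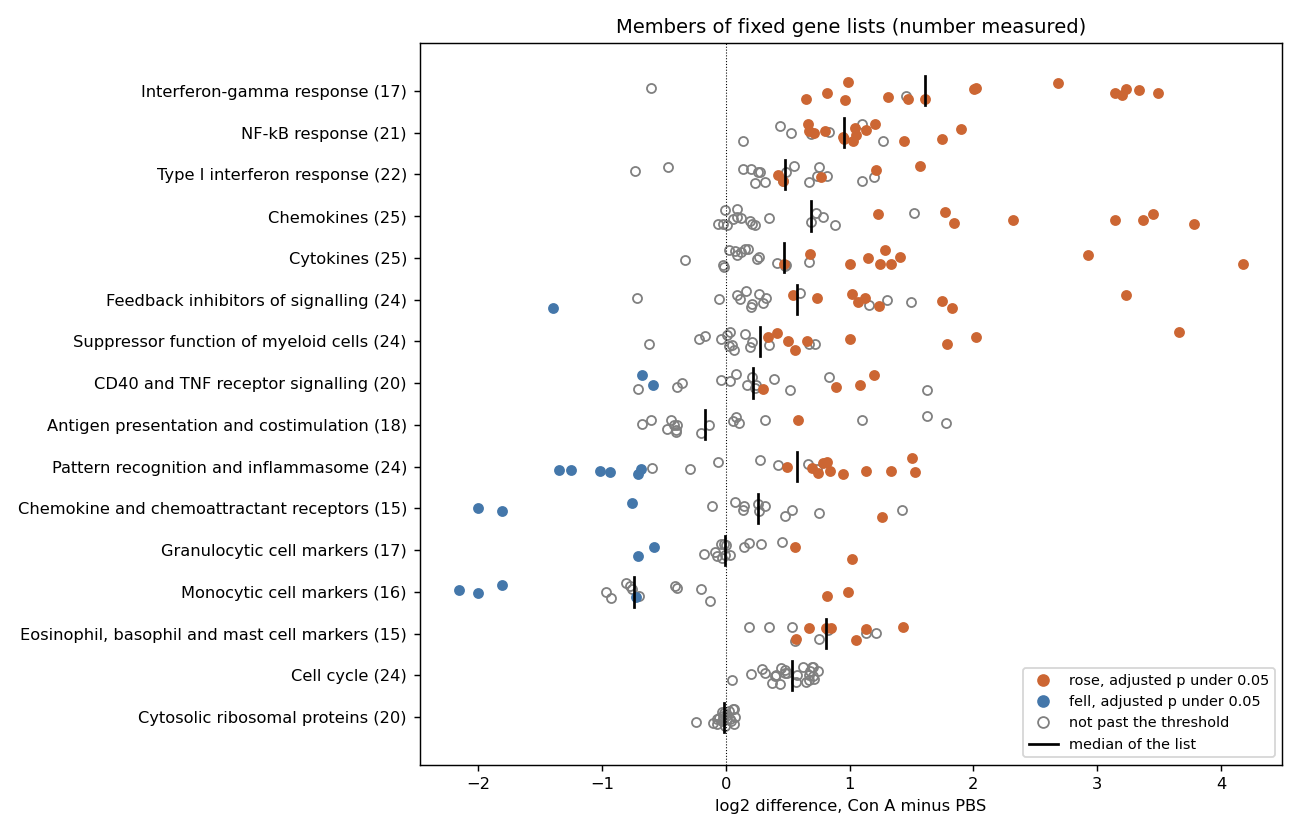
Log2 difference (Con A minus PBS, horizontal axis) of each measured member of 16 gene lists, with filled points for members past the threshold, open points for the others and a bar for the median. The interferon-gamma response has its median at 1.61, the monocytic markers at -0.74 and the ribosomal proteins at -0.01.

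Monocytic cell markers were the 1 list past the threshold that was lower after Con A. Of 16 measured members, 4 fell and 2 rose (11 and 2 adjusted over the list alone), with a median of -0.74. Camera gave 3.9e-05, and adjusted p = 0.762 with an estimated correlation. F13a1, Ccr2 and Cx3cr1 fell by 2.16, 2.00 and 1.81, while Irf8, a transcription factor that interferon-gamma induces, rose by 0.98. Of 17 granulocytic cell markers, 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.913), with a median just below 0, at -0.004, against a mean of 0.06 and an upward camera direction. The decoy receptor gene Il1r2 and the histidine decarboxylase gene Hdc rose by 1.02 and 0.56, and G0s2 and Mmp9 fell by 0.71 and 0.58. The median level of this list was 13.2, near the top of the scale, where differences are understated.

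Eosinophil, basophil and mast cell markers were higher in all 15 measured members, of which 7 rose (11 adjusted over the list alone), with a median of 0.81. Camera gave 3.1e-06, and adjusted p = 0.762 with an estimated correlation. Kit, the stem cell factor receptor gene, rose by 1.43, the granule protein genes Epx and Prg2 by 1.13 and 1.05 and Gata2 by 0.85. The calls of Epx, Prg2 and Gata2 (adjusted p = 0.0459, 0.0418 and 0.0468) ended in 4, 4 and 5 of the 6 fits with 1 array left out, at adjusted p up to 0.161, 0.146 and 0.164, and Epx stood at 10.61 in PBS replicate 2 and 10.66 in Con A replicate 2. Of 11 primary granule genes, 1 rose (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.184, and 0.0385 without PBS replicate 2), and it was the protease gene Ctsg at 0.83. Of 15 secondary and tertiary granule genes, 1 fell (1 adjusted over the list alone; camera adjusted p = 0.676), and it was Mmp9.

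Markers of other liver and blood cells were measured to describe what the sort held. Hepatocyte genes had 0 of 21 members past the threshold (0 adjusted over the list alone), with Alb at 0.86 and Fgb at 0.52 and a camera adjusted p of 0.0196, against adjusted p = 0.807 with an estimated correlation. Their mean lay 0.68 above the PBS mean in Con A replicate 2, and without that array Alb stood at 0.15, Fgb at 0.01 and the adjusted p was 0.48, and without PBS replicate 1 the adjusted p was 0.0517. Of 9 platelet genes, 1 rose (1 adjusted over the list alone), Itga2b by 0.73, with a camera adjusted p of 0.0177 against adjusted p = 0.762 with an estimated correlation. Their mean was 1.42 above the PBS mean in Con A replicate 2 and 0.02 above it in Con A replicate 1, below PBS replicate 3 at 0.11, and the adjusted p was 0.0784 without PBS replicate 3. Of 17 Kupffer cell markers, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.57, and 0.0219 without Con A replicate 1). The mannose receptor gene Mrc1 rose by 1.69, and the iron exporter gene Slc40a1 and Nr1h3 fell by 1.19 and 1.13. Of 19 endothelial and stellate markers, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.282, and 0.0438 without Con A replicate 1), with Pecam1 at 1.55, Fcgr2b at 0.73 and Lyve1 at -1.33.

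Of 13 NK cell markers, 1 rose (1 adjusted over the list alone), the granzyme gene Gzmb by 1.75. The camera adjusted p was 0.493, and 7.8e-05 without Con A replicate 2. T cell and EL4 markers had 0 of 17 members past the threshold (0 adjusted over the list alone; camera adjusted p = 0.157, and 0.0354 without Con A replicate 1), with Il7r at 0.46 (95% interval -1.28 to 2.20) and Cd28 at 0.30. Il7r stood at 1.31 without PBS replicate 3 and at -0.13 without PBS replicate 1. Of 14 B cell markers, 1 fell (1 adjusted over the list alone), Ms4a1 by 0.45, and the camera adjusted p was 0.253, and 0.0141 without PBS replicate 3. Of 15 dendritic cell markers, 1 fell (1 adjusted over the list alone; camera adjusted p = 0.913), Wdfy4 by 0.66. Of 9 erythroid genes, 1 rose (1 adjusted over the list alone; camera adjusted p = 0.157), Car2 by 0.53.

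**Figure D3:**
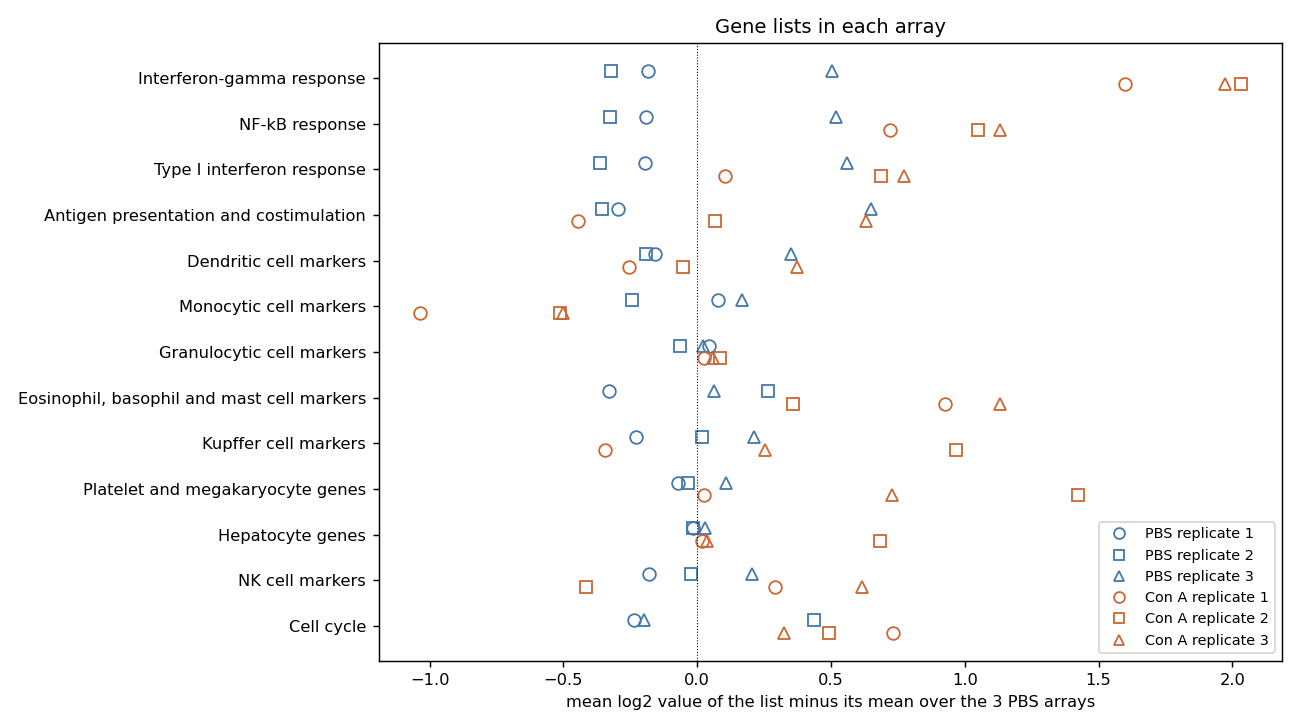
Mean log2 value of 13 gene lists in each array, relative to the mean of the 3 PBS arrays (horizontal axis), with colours for the group and symbols for the replicate. PBS replicate 3 lies 0.65 above the PBS mean for antigen presentation, and Con A replicate 2 lies 0.68 above it for hepatocyte genes and 1.42 above it for platelet genes.

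Among metabolic and structural lists, coagulation and fibrinolysis had 5 of 17 members that rose and 3 that fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.368). F3, which encodes tissue factor, rose 9.14-fold from 6.93 ± 0.15 to 10.13 ± 0.60, and Serpinb2 and Thbs1 rose by 2.37 and 1.76. Glycolysis and hypoxia genes rose in 7 of 23 cases and fell in 3 (7 and 4 adjusted over the list alone; camera adjusted p = 0.166, and 0.0496 without Con A replicate 1), with the oxygen sensor gene Egln3 at 1.66, Pfkl at 1.12, Bnip3 at 1.10 and the glucose transporter gene Slc2a1 at 1.03. Of 18 apoptosis and survival genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.09, and 0.0202 without PBS replicate 3, 0.0408 without Con A replicate 1 and 0.0315 without Con A replicate 2), with Bcl2l1 and Cflar, which encode inhibitors of cell death, at 0.88 and 0.86. Of 22 adhesion and migration genes, 5 rose and 6 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.489), with Icam1 at 1.90, Vcam1 at 1.15 and the integrin gene Itga4 at -0.95. This list had a median of -0.10 and a downward camera direction but a mean of 0.04.

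Cell cycle genes were higher in all 24 measured members, and 0 passed the test on their own (0 adjusted over the list alone), with Top2a at 0.74 and Cdk1 at 0.71. Camera gave 6.7e-06, and adjusted p = 0.762 with an estimated correlation, and the list mean of PBS replicate 2, at 0.44, lay above that of Con A replicate 3, at 0.32. Top2a and Cdk1 each missed the threshold in 15 of 17 alternatives, and their lowest limma adjusted p was 0.0182 and 0.0236. Of 23 reactive oxygen and antioxidant genes, 1 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.253), with Sod2 at 0.71, Cat at -0.51, Nqo1 at -0.44 and Sod1 at -0.38. The calls of Cat, Nqo1 and Sod1 ended in 4, 6 and 5 of the 6 fits with 1 array left out, at adjusted p up to 0.122, 0.128 and 0.126. Of 18 prostaglandin and leukotriene genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.966), with Ptges at 0.66, Ptger2 at -0.71 and Tbxas1 at -0.34, and the median of -0.03 and the camera direction were downward while the mean was 0.08. Of 22 heat shock genes, 1 fell (0 adjusted over the list alone; camera adjusted p = 0.184), Sdf2l1 by 0.36. Oxidative phosphorylation had 0 of 25 members past the threshold (0 adjusted over the list alone; camera adjusted p = 0.676), with Cox7a2 at 0.25 and Cycs at 0.21. Ribosomal proteins had 0 of 20 (0 adjusted over the list alone; camera adjusted p = 0.676), with Rplp2 at -0.24 and Rps9 at -0.10.

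Altogether 15 of 38 lists passed with camera at the preset correlation, 14 higher and 1 lower, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. Fry called 2 lists in 1 direction and 29 for change in either direction.

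Of 96 named genes past the threshold, 59 passed with each array left out in turn and 37 missed it in at least 1 of these 6 fits, where their highest adjusted p lay between 0.0503 and 0.164. Besides Cd80, Epx, Prg2, Gata2, Cat, Nqo1 and Sod1, they were Ier3, Fas, Map3k14, Csf1, C3ar1, Zbp1, Irf7, Ddx58, Sod2, Ctsg, Il1r2, Irf8, Wdfy4, Gzmb, Ms4a1, Lyve1, Fcgr2b, Car2, Maff, Myc, Klf2, Sdf2l1, Tlr9, Clec7a, Vcam1, Itga4, Slc2a1, Tbxas1, Pim1 and Bcl3.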

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

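No result changed direction while past its threshold under any alternative run, with lists taken by their camera direction. The median of the antigen presentation list did change sign. It was -0.17 in the main fit and 0.07 without PBS replicate 3, where the camera adjusted p was 0.0413. With each array left out in turn, genes that differed numbered 1140 to 2765 (458 to 1114 higher, 682 to 1651 lower), those of 2-fold or more 322 to 545, and lists 12 to 22 (11 to 21 higher, 1 to 2 lower). Leaving out an array also removes degrees of freedom. The unmoderated test, which drops the pooled variance, gave 671 genes, 290 higher and 381 lower, of which 630 were shared with the 2355. Testing all rows of the table counts rows in place of genes, so its counts do not compare directly. It gave 676 rows of 2-fold or more, 393 higher and 283 lower. Of these, 418 had 1 symbol, 17 several and 241 none. Camera with an estimated correlation called 0 lists (0 higher, 0 lower) and fry called 2 (2 higher, 0 lower). Estimated correlations ran from -0.07 to 0.87 against the preset 0.01, and for fry the cause was not tested. The fit without both PBS replicate 3 and Con A replicate 2 was chosen after seeing the data. It gave 1947 genes, 508 of 2-fold or more and 19 lists, 2 of them lower (monocytic and B cell markers), and the cause was not tested. Fitted with the replicate number as a block, 2539 genes differed, 455 of them by 2-fold or more, and Cd40 had an adjusted p of 0.00331. Cd40 passed under 8 of its 17 alternatives, with adjusted p from 0.00331 to 0.227. The deviations of same-numbered arrays correlated at 0.228, -0.17 and 0.555. Deviations from the mean of 3 arrays cannot tell if the numbers pair the samples, and the labels do not say. Quantile normalization and a common median moved the median of all genes from 0.02 to 0.03, and the share of calls that were higher from 38.9% to 44.4% and 40.3%. Of the values of named genes under the alternatives, 1700 kept their side of the threshold, 234 lost it and 13 gained it. For lists these were 578, 42 and 26. Signal near the top of the scale limits what can be seen for granulocyte genes, and signal near the bottom for dim ones.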

Other observations

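The tests in this part on gene families were chosen after the results were seen, as were those on antigen-presenting cells and batch, on the monocytic list, on the share of eosinophils and related cells and on the monocytic markers within that pattern. Genes were grouped by the stem of their symbol, and 309 families with at least 8 members were tested for an excess of genes past the threshold in each direction (Fisher's exact test, one-sided, adjusted over 618 tests). This test takes genes as independent, whereas genes of the fixed lists had estimated correlations up to 0.87, so its p-values may be too small. Its background held genes of every level, with no filter for dim ones. A family with a larger share of expressed genes can therefore exceed the background for that reason alone. Genes named Zfp, mostly zinc finger proteins, fell in 59 of 347 cases where 25.3 would match the background (adjusted p = 4.7e-07), while 11 rose and the family median was -0.07. Zfp710 fell by 1.21, Zfp652 by 1.09 and Zfp36l2 by 0.94. The share of Zfp genes that fell was 17.0% against 7.3% of the background, 14.7% against 6.39% after quantile normalization and 15.3% against 6.73% at a common median. With 1 array left out, 33 (9.51% against 3.36%, without PBS replicate 1) to 61 Zfp genes fell, and without Con A replicate 2 it was 36 (10.4% against 3.46%). Of 364 genes with the stem Slc, mostly solute carriers, 47 fell where 26.6 would match the background (Fisher's exact test, adjusted p = 0.0145). Slc9a3r2, which is not a transporter gene, was among those that fell. Another 16 rose, Slc7a2 by 3.66 among them, with a family median of 0.01, so the family did not fall on the whole. The count that fell was 27 without PBS replicate 1 (7.42% against 3.36% of the background) and 31 without Con A replicate 2 (8.52% against 3.46%). Genes with the stems Gbp, Irf, Cxcl and Casp rose in 6 of 8, 6 of 11, 5 of 13 and 4 of 9 cases (Fisher's exact test, adjusted p = 5.0e-05, 0.0005, 0.0175 and 0.0373). Several of these were also in the fixed lists. The Irf stem took in Irf2bp2, 1 of the 6 that rose, which is not itself an interferon regulatory factor. With 1 array left out, 6 to 8 Gbp genes rose. The Irf count was 1 without PBS replicate 1, Con A replicate 2 or Con A replicate 3, and 3 without PBS replicate 2 or Con A replicate 1. The Cxcl count was 3 without PBS replicate 1, Con A replicate 2 or Con A replicate 3. The Casp count was 2 without PBS replicate 1, PBS replicate 2, Con A replicate 2 or Con A replicate 3. At a common median the Casp count was 3. The Casp genes that rose were Casp4, Casp6, Casp8 and Casp12, and the Cxcl genes were Cxcl11, Cxcl10, Cxcl9, Cxcl3 and Cxcl2. Casp12 lay near the bottom of the scale, at 3.95 after PBS and 4.32 after Con A (limma adjusted p = 0.0465).

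The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes that differed, 1 of 10 splits gave as many as the real 2355, and the highest other split gave 0. For 2-fold genes 1 of 10 gave as many as the real 412, and the highest other gave 0. For lists 5 of 10 gave at least the real 15, and the highest other gave 26. That split set PBS replicates 1 and 2 and Con A replicate 1 against the rest, which points to a structure of the arrays that camera at its preset correlation also reads.

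PBS replicate 3 stood apart from the other PBS arrays, with correlations of 0.9906 and 0.9891 with them against 0.9962 between them, and Ccl17, Ccl22 and Cd209a, named after their values were seen, lay 2.61, 2.56 and 1.94 above their mean. A Con A array under a wrong label is argued against, since over genes called without this array its median position was 0.297 (quartiles 0.0549 to 0.545) on a scale from 0 for PBS to 1 for Con A. More dendritic or other antigen-presenting cells in that sort stays open. Of the antigen presentation and dendritic list members, 87.5% (28 of 32) were highest there among PBS arrays, against 32.6% of all genes. So were 100% of NF-kB, 95.5% of type I interferon, 93.8% of interferon-gamma and 68% of chemokine members. These are response lists and not cell markers, but the chemokine list holds Ccl17 and Ccl22, so they may not be free of genes of such cells. The CD11b+Gr-1+ gate may remove many dendritic and other antigen-presenting cells. A batch shared by the arrays numbered 3 stays open, since their deviations correlated at 0.555 but PBS replicate 2 and Con A replicate 1 reached 0.538. A difference between animals was not tested.

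Of 16 monocytic markers, 4 fell after Con A and 2 rose, with a median of -0.74, and the call of the list was lost with an estimated correlation (adjusted p = 0.762). A lower share of monocytic cells stays open as part of the cause, since 14 of 16 members were lower, which lower expression could give too. As the only cause it would lower markers that only these cells express by a like amount. That 2 members rose argues against it as the only cause, as far as the members mark only these cells. The lower members ran from -2.16 to -0.13. This range cannot decide it, since compression near the ends of the scale can also make differences unlike in size. Lower expression in an unchanged share of cells stays open as well, since the lower members differed in size, with an SD of their differences 3.08 times their median SE. This ratio replaced a heterogeneity p of 4.4e-32 after that p had been seen, because the p rests on a normal approximation that 3 arrays per group do not bear, and both measures leave the explanation open. The treatment itself is the biological difference in the design.

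Of 15 eosinophil, basophil and mast cell markers, 7 rose after Con A, with a median of 0.81, and the call of the list was lost with an estimated correlation (adjusted p = 0.762). A lower share of the main granulocytic population, which raises every other type alike, stays open. The monocytic markers had a median of -0.74 with quartiles of -0.94 and -0.35, below the quartiles of this list, 0.57 and 1.09. They cannot decide it, since a lower monocytic share or lower expression, both left open, could hide such a rise. The planned test over 32 markers of 9 other lists above a level of 8 did not decide it either, with a median of 0.0723 and quartiles of -0.23 and 0.69. A larger share of these cells in the Con A sorts stays open, since 100% of the members (15 of 15) were higher, which higher expression per cell could give too. Prg2 and Epx stood at 11.98 and 11.16 after Con A, and the CD11b+Gr-1+ gate may remove part of these cells.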
